A study of Mus musculus with 4 samples.

How the data were processed

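Single cells from whole kidneys of mice on postnatal day 1 were measured by Drop-seq, a droplet method that reads the 3′ end of each transcript and tags each molecule with a unique molecular identifier (UMI). There were 4 libraries, 1 for cells released with a cold-active protease and 1 each for cells released with an enzyme cocktail for 15, 30 or 60 minutes. The labels give no digestion time for the cold library and no temperatures. With 1 library per group there were no replicates, so no test between groups was made and no p-value or standard error is given.

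The authors deposited 2 tables per library. The first holds whole-number UMI counts per gene and barcode, and all main results were computed from these deposited counts. The second holds a signal on a linear scale that the authors made by scaling the counts of each barcode to a total of 10000, as recomputing it from the counts showed; it served as an alternative. Per the submitters' processing notes, reads were handled with Bowtie2 2.2.7 and the mm10 build; the annotation, the counting step and the collapsing of UMIs are not given in the sources used here. The authors also deposited lists of cold-library barcodes for 9 cell types, which were set beside the clusters described here. The tables held 28340 gene symbols in all, of which 26369 (93.0%) matched a gene name in GENCODE M21, and coordinates were taken from that annotation for the 135 of 138 named genes with 1 match.

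A barcode was kept as a cell if it had at least 500 genes. The deposited tables of the cold, 30-minute and 60-minute libraries held no barcode below this number; that of the 15-minute library held 15000 barcodes, 4 of them empty, of which 11523 were kept. No barcode was removed for its mitochondrial share, since this may itself differ with digestion. Cells kept numbered 9856, 11523, 11913 and 8401 in the cold, 15-, 30- and 60-minute libraries, with 29174401, 38353672, 45134942 and 29656445 UMIs. Predicted doublets stayed in the sums. Scrublet, run in scanpy 1.11.5 with an expected rate of 0.06, called 0, 0, 0 and 1 cells at its own threshold, so its calls removed almost nothing; leaving out the 6% of cells with the highest score in each library was added after the data were seen.

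UMIs were summed over the cells of each library and scaled to CPM, the counts out of 1e6 UMIs of the library. The log2 ratio of CPM was computed per gene for each digestion time to cold and for 60 to 15 minutes, with the exact conditional binomial (Clopper-Pearson) 95% interval of a ratio of 2 Poisson counts. All intervals cover counting error only, not the difference between mice or between repeated digestions. Genes with at least 50 CPM in either library of a comparison were described, by a fixed size of 2-fold. A library with 0 UMIs was set to 3 counts, and the ratio is then given as a bound. Mitochondrial, ribosomal protein, haemoglobin and sex-linked genes were left out of the ranking that chose named genes, though not of the lists or the counts of genes.

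Genes were named by a rule: the 12 highest and the 12 lowest ratios for 60 minutes to cold, the 5 highest and 5 lowest for each other comparison, the 3 highest in each cell class at 60 minutes, up to 6 members of each list with the largest ratio in either direction, and the genes for which shares of cells are given. Some genes picked by this rule or used as markers are not reported here. There were 25 fixed lists: 12 of responses (immediate early, heat shock, NF-kB targets, unfolded protein and integrated stress response, p53 targets, hypoxia and glycolysis, oxidative stress and metal, mitochondrially encoded, nuclear-retained RNA, S phase, G2/M phase and sex-linked genes) and 13 of kidney cell type markers. A list's median log2 ratio was set against 10000 random lists of the same size matched on expression in 20 bins. The gene lists, comparisons, filters, rule for named genes and the alternatives, apart from those said to be added later, were fixed before the data were examined.

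Kept cells of the 4 libraries were clustered together on 1500 variable genes, 30 principal components and 15 neighbours with the Leiden method (leidenalg 0.10.2) at resolution 1, with genes scaled within each library. Genes of the response lists and genes at least 2-fold different from cold at any time were left out of the clustering, and the latter included some markers. Each cluster took the class whose markers scored highest, if at least 3 markers were 2-fold higher than in other cells. After the data were seen, a rule was added: a cluster stayed unnamed if the leading marker among its 10 top genes belonged to another class, or if most of its cells with a type from the authors had a type of another class. For this, the authors' nephron progenitors were taken to match nephron progenitor or nephron intermediate markers and their stromal cells stroma or mural markers; the authors' lists used here hold no leukocyte or intercalated type, so clusters with those markers were not held to it. The macrophage-like cluster was named in this way, although 59.0% of its 39 cells with a type from the authors were nephron progenitors. The class names are thus rebuilt here, not taken from the authors, and are written as "-like". Of 31 clusters, 5 stayed unnamed, and no cluster was named for erythroid or intercalated cells, which left 11 classes. Ratios within a class were made where both libraries had at least 30 of its cells. For shares of cells with a UMI of a gene, each cell was thinned to 800 UMIs, cells with fewer were left out, and exact binomial intervals were computed.

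The method was tested on simulated data for 60 minutes to cold with the depths of those libraries and 3322 genes. The simulated counts held counting error only, the same error that the intervals assume, so coverage near 95% follows from the setup. They held no variation between cells, mice or repeated digestions. The test therefore does not tell how often such variation would bring a gene to 2-fold. For 60 minutes to cold, 94.5% of the intervals of the 3122 genes simulated without a difference held the true value, and 0 of these genes came out at 2-fold or more. For 60 minutes to cold, 95% of the intervals of the 100 genes simulated at 2-fold and 98% of those of the 100 genes simulated at 4-fold held the true value; 49 and 100 of them came out at 2-fold or more, with 0 in the wrong direction. Correlations between comparisons that share the cold library were set beside those from 100 simulations with shared cold counts and no effect.

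The alternatives were: at least 300 or 1000 genes per cell, or every deposited barcode; median-of-ratios size factors, TMM factors from edgeR 4.0.16 (R 4.3.3) and totals without mitochondrial, ribosomal protein and haemoglobin genes; the mean over cells of per-cell fractions; each class weighted alike in every library; the macrophage-like class left out; cells over 25% mitochondrial left out; doublets left out; a minimum of 10 CPM, or no minimum beyond 1 UMI in both libraries; the deposited normalized signal; and, for the classes, all variable genes, 0.5 and 2 times the resolution, scaling over all libraries together, and at least 1000 genes. Computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and scikit-learn 1.9.0.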

Results

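The data were UMI counts from Drop-seq of whole kidneys of mice on postnatal day 1, in 4 libraries that differed in how the tissue was turned into single cells. In 1 library a protease active in the cold was used, and in the other 3 a cocktail of enzymes acted for 15, 30 or 60 minutes. The series title names the question, whether digestion itself alters the expression measured in single cells. The cold library held 9856 cells and 29174401 UMIs, the 15-minute library 11523 cells and 38353672 UMIs, the 30-minute library 11913 cells and 45134942 UMIs, and the 60-minute library 8401 cells and 29656445 UMIs. Median UMIs per cell were 1759.5, 1642, 1735 and 1978 in that order, and median genes per cell 996, 944, 993 and 1046. Mitochondrial genes took 12.04% of UMIs in the cold library and 8.85%, 9.63% and 9.47% in the 15-, 30- and 60-minute libraries, and the share of cells over 25% mitochondrial was 9.78%, 3.76%, 5.36% and 4.21%. Ribosomal protein genes took 10.7%, 12.6%, 11.1% and 13.3% and haemoglobin genes 0.223%, 0.274%, 0.106% and 0.221%. The most abundant gene in every library was mt-Rnr2, the mitochondrial large ribosomal RNA, at 9.33%, 6.50%, 7.07% and 6.61% of UMIs. Each group was 1 library without a replicate, so the differences below describe these libraries, and the brackets give 95% intervals that cover counting error only.

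After 60 minutes of enzyme digestion, transcripts of the immediate early genes, which cells switch on within minutes of a stimulus, were far higher than in the cold library. Fosb and Fos, which encode subunits of the AP-1 transcription factor, were 2250-fold and 516-fold higher, and Atf3, a stress-induced transcription factor gene, was 195-fold higher. The NF-kB targets Irf1, Nfkbiz and Nfkbia, the p53 targets Cdkn1a and Gadd45a and the inducible heat shock gene Hspa1a were also higher, by less. The transcription factor genes Emx2, Lhx1 and Gata3, each with a known role in kidney development, were lower. Of 3592 genes with at least 50 CPM in either library, 98 were at least 2-fold higher at 60 minutes than in cold and 11 at least 2-fold lower, while 87.2% lay within 0.5 log2 units. At least 4-fold, 38 were higher and 1 lower, and at least 8-fold, 25 were higher and 0 lower.

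The immediate early list held 25 measured members at 60 minutes, 24 of them at least 2-fold higher than in cold, with a median log2 ratio of 3.79 (3.72 to 3.85), above all of 10000 random lists of like expression. Fosb had 5 UMIs in the cold library and 11434 at 60 minutes, a log2 ratio of 11.14 (9.91 to 12.76); in mm10 the protein-coding gene lies on chromosome 7 from 19302696 to 19310051. Fos, on chromosome 12 from 85473890 to 85477273, had 49 and 25683 UMIs, a log2 ratio of 9.01 (8.61 to 9.45). Atf3, on chromosome 1 from 191170296 to 191218039, had 91 and 17995 UMIs, a log2 ratio of 7.60 (7.31 to 7.92). Nr4a1, an orphan nuclear receptor gene on chromosome 15 from 101254269 to 101274795, had a log2 ratio of 5.97 (5.71 to 6.24). Socs3, an inhibitor of cytokine signalling, stood at 5.38, the AP-1 gene Junb at 5.32, the matricellular gene Cyr61 at 5.17, and Zfp36, whose protein promotes decay of AU-rich mRNAs, at 5.06. Gdf15, a stress-induced secreted factor, stood at 4.58, the growth arrest gene Gadd45b at 4.41, the small Maf gene Maff at 4.37 and Csrnp1, a nuclear protein gene, at 4.35. These 12 were the highest genes of the comparison. Jun, at 3.79 (3.72 to 3.85), and Egr1, a zinc finger transcription factor gene at 4.003 (3.89 to 4.11), were present in the cold library at 71.0 and 24.1 CPM and were at 979 and 386 CPM at 60 minutes.

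The heat shock, NF-kB, p53, unfolded protein and hypoxia lists were also higher at 60 minutes, by less. The heat shock list had a median log2 ratio of 0.44 (0.41 to 0.47) over 15 members, of which 4 were at least 2-fold higher, at percentile 99.98 of random lists. Its highest members were Hspa1a at 3.34 (3.11 to 3.58), Dnajb4 at 1.81, Hspb1 at 1.29 and Dnajb1 at 1.06, whereas the constitutive Hspa8 was at 0.85. Hspa1a lies on chromosome 17 from 34969190 to 34972156. Hspa1b, its near-identical neighbour, was below 50 CPM and stood at 1.51. The NF-kB list had 4 of its 20 members measured and a median of 2.67 (2.59 to 2.73). Its measured members were Irf1 at 3.18, Nfkbiz at 3.10, the inhibitor Nfkbia at 2.25 and the mitochondrial dismutase gene Sod2 at 0.10. Irf1 and Nfkbiz, at 5.83 and 14.5 CPM in cold, passed the 50 CPM minimum only through the 60-minute library. So did the 4 heat shock genes at 2-fold, which ran from 5.86 CPM (Hspa1a) to 30.1 CPM (Hspb1) in cold. The minimum thus favours members that were higher at 60 minutes, which also bears on the counts at 2-fold. The p53 list had 3 of its 16 members measured, of which the cell cycle inhibitor Cdkn1a was at 1.45, Gadd45a at 1.51 and the apoptosis gene Bax at 0.23. Cdkn1a and Gadd45a, at 46.3 and 46.2 CPM in cold, also passed the minimum only through the 60-minute library. The unfolded protein and integrated stress response list had a median of 0.19 over 13 members, and 4 of them were at least 2-fold higher: Ppp1r15a at 3.602, Ddit3 at 2.05, Dnajb9 at 1.30 and Atf4 at 1.15. Of these, Ppp1r15a, Ddit3 and Dnajb9, at 11.6, 14.7 and 20.9 CPM in cold, passed only through the 60-minute library, unlike Atf4. The chaperone gene Calr, on that list, was at 0.20. The hypoxia and glycolysis list had a median of 0.28 with 0 of 9 members at 2-fold, led by Gapdh at 0.83. The oxidative stress and metal list had a median of 0.15 over 8 members, at percentile 93.5 and within the central 95% of random lists, with Sqstm1 at 0.89 and Txnip at -0.63. With TMM or median-of-ratios scaling, every log2 ratio of 60 minutes to cold was higher by 0.11 or 0.13, so that values near 0 carry that uncertainty.

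Among genes lower at 60 minutes, Rprm, a p53-induced cell cycle arrest gene on chromosome 2 from 54084093 to 54085552, was lowest at a log2 ratio of -2.04 (-2.16 to -1.93). Emx2, a homeobox gene needed for the ureteric bud and nephron, lies on chromosome 19 from 59458372 to 59465357 and stood at -1.69 (-1.77 to -1.61). Also among the 12 lowest were Zfp503 at -1.22, Lhx1 at -1.12, the Wnt receptor gene Fzd7 at -1.05, Gata3 at -1.01 and Pou3f3 at -0.99. Linker histone genes Hist1h1b and Hist1h1e, expressed in S phase, were at -1.47 and -1.18, and Fbxo5, an inhibitor of the anaphase-promoting complex, was at -1.08. Tril, a Toll-like receptor accessory gene, was at -1.02. The G2/M list had a median of -0.28 (-0.31 to -0.22) over 13 members, at percentile 0.615 of random lists, with Mki67 at -0.89 and Cenpf at -0.86, and the S phase list a median of -0.11 over 11 members at percentile 56.0. The size of the lower set depended on the expression minimum: at 10 CPM instead of 50, 110 genes were at least 2-fold lower and 197 higher of 9501. It also depended on scaling and on how cells were weighed, with 6 lower under median-of-ratios scaling, 7 under TMM and 21 when each cell weighed the same.

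Cell type marker lists at 60 minutes to cold had medians on both sides of 0. These were -0.37 for nephron progenitors, -0.31 for nephron intermediates, -0.31 for podocytes, 0.19 for proximal tubule, -0.32 for the loop of Henle, 0.03 for distal tubule, 0.14 for ureteric and collecting duct, 0.07 for stroma, 0.29 for mural cells, -0.09 for endothelium, -0.06 for erythroid and 0.10 for intercalated cells, and no macrophage marker reached 50 CPM. The loop of Henle and podocyte medians, at percentiles 0.25 and 2.02, lay below the central 95% of random lists, and those for mural cells and proximal tubule, at 97.9 and 98.6, above it. Some lists had few measured members: 2 for nephron progenitors (-0.72 and -0.02), 2 for intercalated, 3 for mural and 3 for endothelial cells. The podocyte median was 0.09 and the proximal tubule median -0.13 when each cell weighed the same. With at least 1000 genes per cell the mural median was -0.76, the value of Ren1 itself. The keratin gene Krt18, a member of the ureteric and collecting duct list, stood apart at 1.79 (1.74 to 1.83). The renin gene Ren1, made by juxtaglomerular cells and on the mural list, was at 1.34 (1.25 to 1.43), though at -0.76 among cells with at least 1000 genes. The mitochondrially encoded list had a median of 0.07 with mt-Atp6 at 0.53 and mt-Nd6 at -0.66. The nuclear-retained list was at -0.30 over 3 members, with Malat1 at -0.30 and Neat1 at 0.50. The sex-linked list was at 0.05 over 3 members, a median that hides values on both sides of 0. Xist, which was on both lists, stood at -0.35, and the highest sex-linked member at 0.30.

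**Figure D1:**
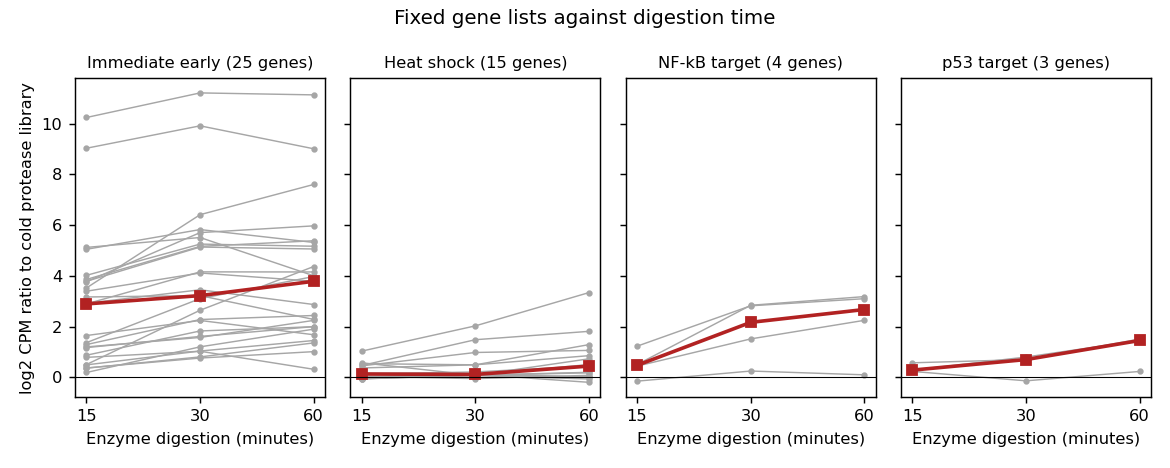
Log2 CPM ratio to the cold library (y axis) at 15, 30 and 60 minutes (x axis) for each member of 4 fixed lists in grey, with the median of the members drawn in red. For the 25 immediate early genes drawn, the median was 2.89, 3.22 and 3.79 in that order, and for the 15 heat shock genes 0.13, 0.11 and 0.44.

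At 15 minutes, the shortest enzyme digestion, the immediate early genes already stood apart from the cold library. Fosb was 1213-fold higher, with 7971 UMIs against 5, and Fos 523-fold higher, with 33719 against 49. Egr1 was 34.8-fold, Junb 33.1-fold and Cyr61 16.2-fold higher. Of 3562 genes at 50 CPM, 20 were at least 2-fold higher than in cold, 15 of them on the immediate early list, and 0 were at least 2-fold lower; when each cell weighed the same, 39 were lower, and at 10 CPM 49 were higher. The list's median log2 ratio was 3.17 (3.10 to 3.23) over 19 members, above all random lists. It depended on the expression minimum, with 2.27 at 10 CPM and 1.65 with no minimum beyond 1 UMI in both libraries. Heat shock genes had a median of 0.03, at percentile 45.6 of random lists, with 0 of 11 members at 2-fold. Below the expression minimum, Hspa1a, at 11.99 CPM, stood at 1.03 (0.78 to 1.29) and Hspa1b, at 8.68 CPM, at -0.09. The unfolded protein and integrated stress response list was at 0.08, with 1 of 10 members, Ppp1r15a, at 2-fold and a log2 ratio of 2.13 (1.96 to 2.30). The NF-kB list was at 0.14 over 2 members, while Nfkbiz, at 33.8 CPM and thus below the minimum, stood at 1.23 (1.07 to 1.39). The p53 list was at 0.28 over 3 members, at percentile 99.04 of random lists, the hypoxia list at 0.04, and the oxidative stress and metal list at -0.05.

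Cell type markers differed at 15 minutes in both directions. Stroma and mural marker lists were higher, with medians of 0.71 and 0.77, and Ren1, on chromosome 1 from 133350510 to 133360325, was higher by 2.199 (2.12 to 2.28). The collagen genes Col1a1 and Col3a1 stood at 0.94 and 0.87. Endothelial, podocyte, erythroid and nephron progenitor markers had medians of 0.34, 0.29, 0.29 and 0.14, and nephron intermediate markers 0.04. Measured members were few for the mural (4), endothelial (3), nephron progenitor (2), intercalated (2), nuclear-retained (3) and sex-linked (2) lists. Tubule lists were lower, at -0.54 for the loop of Henle, -0.39 for distal tubule, -0.31 for proximal tubule, -0.30 for ureteric and collecting duct and -0.41 for intercalated cells; the proximal tubule median was 0.06 among cells with at least 1000 genes. The lowest genes were Slc12a1, the salt cotransporter of the thick ascending limb, at -0.76 (-0.79 to -0.74), the osmotic response factor Nfat5 at -0.76, the mitochondrial biogenesis regulator Ppargc1a at -0.71, Wwc1 at -0.69 and the tight junction gene Cldn19 at -0.68. The mitochondrially encoded list was at -0.19, nuclear-retained RNA at -0.36, S phase at 0.12, G2/M at 0.16 and sex-linked genes at -0.11. With each class weighted alike in every library, the stroma median was 0.037, the podocyte median -0.08 and that of distal tubule 0.02.

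At 30 minutes Fos, Fosb and Egr1 stood at their highest level of the 3 times. Fosb was 2374-fold, Fos 966-fold and Egr1 45.6-fold higher than in cold, and Atf3 and Nr4a1 were 85.2-fold and 52.2-fold higher. The 5 highest genes, Fosb, Fos, Atf3, Junb and Nr4a1, had log2 ratios from 11.21 to 5.71. Of 3594 genes, 42 were at least 2-fold higher, 20 of them immediate early, and 4 were lower; at 10 CPM, 88 were higher and 7 lower. The 4 lower genes were the haemoglobin genes Hba-a1, Hba-a2, Hbb-bs and Hbb-bt, at -1.06, -1.05, -1.11 and -1.02, and the erythroid list was at -1.06. With TMM factors 2 genes were lower, with each cell weighed the same 1, and with classes weighted alike 0. The immediate early median was 4.11 (4.04 to 4.17) over 21 members, although it was 3.22 over the 25 members measured at 60 minutes. NF-kB targets had a median of 1.51 over 3 members, with Nfkbiz at 2.82 and Nfkbia at 1.51, and p53 targets a median of 0.70. The unfolded protein and integrated stress response list was at 0.16, with 1 of 11 members, Ppp1r15a, at 2-fold and a log2 ratio of 3.17 (3.01 to 3.34). The heat shock list was at 0.10, percentile 87.2, with 1 of 13 members, Dnajb4, at 2-fold; Hspa1a, at 23.9 CPM, was below the expression minimum and was higher by 2.03.

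Other lists at 30 minutes had medians on both sides of the cold level. Only 2 nephron progenitor members were measured, and 3 each for the mural, endothelial, intercalated, nuclear-retained and sex-linked lists. The sex-linked members ran from -0.32 to 0.33. The lowest of them, Xist, was also on the nuclear-retained list and gave its median. Hypoxia and glycolysis genes were at 0.17, oxidative stress and metal genes at 0.11, mitochondrially encoded genes at -0.05, nuclear-retained RNA at -0.32, S phase at 0.15, G2/M at 0.06 and sex-linked genes at 0.13. Among cell types the podocyte list was at -0.33, loop of Henle at -0.12, nephron progenitor at -0.05, nephron intermediate at 0.07, stroma at 0.01, endothelium at 0.07, distal tubule at 0.08, ureteric and collecting duct at 0.02, proximal tubule at 0.00, intercalated at 0.12 and mural at 0.39. Below the central 95% of random lists were the podocyte, nuclear-retained and loop of Henle medians, at percentiles 0, 0.045 and 1.2, and above it were those for mural cells, S phase and hypoxia, at 99.8, 99.5 and 98.6. The podocyte median was 0.09 when each cell weighed the same, that of the loop of Henle 0.01 without cells over 25% mitochondrial, and that of mural cells -0.05 with classes weighted alike and -0.21 among cells with at least 1000 genes. The lowest genes outside the haemoglobins were Hist1h1b at -0.71, Nfat5 at -0.69, the water channel gene Aqp2 at -0.69, the small nucleolar RNA host gene Snhg7 at -0.68 and Emx2 at -0.66.

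Genes followed different courses over the 3 digestion times. Fos and Egr1 were highest at 30 minutes, and Egr1 was lower at 60 minutes than at 15, by a log2 ratio of -1.12 (-1.15 to -1.09). Atf3 was higher at each later time, by 3.52, 6.41 and 7.60 over cold. A later group was at most 1.55-fold higher than cold at 15 minutes and far higher at 60: Maff (0.50, then 4.37), Cldn4, a tight junction gene (0.63, then 3.94), and F3, the gene of coagulation tissue factor (0.27, then 3.80). At 15 minutes and in cold Maff was at 7.48 and 5.28 CPM and F3 at 12.9 and 10.7 CPM, all below the expression minimum. Sprr1a, a cornified envelope gene induced by stress, was lower than cold at 15 minutes at -2.55 (-3.01 to -2.11), with 52 UMIs against 231 at 1.36 and 7.92 CPM, below the minimum, and higher at 60 minutes at 3.38 (3.19 to 3.59). Between 60 and 15 minutes directly, 65 of 3532 genes were at least 2-fold higher and 11 lower. The highest were Sprr1a at 5.93, Atf3 at 4.08, Maff at 3.86, F3 at 3.53 and Cldn4 at 3.31. Cldn4 lies on chromosome 5 from 134945119 to 134946934, F3 on chromosome 3 from 121723537 to 121735048, and Sprr1a on chromosome 3 from 92483952 to 92485895. Among the lowest were the stromal and podocyte transcription factor gene Tcf21 at -1.63, Rprm at -1.54, Hist1h1b at -1.26 and Fbxo5 at -1.24.

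Across the genes at least 2-fold higher than cold at any time, apart from mitochondrial, ribosomal protein, haemoglobin and sex-linked genes, 86 of 104 were highest at 60 minutes, 15 at 30 minutes and 3 at 15 minutes. In 78 of the 104 the ratio was higher at each later time. The genes were chosen on these same ratios, and with 98 genes past 2-fold at 60 minutes, beside 42 and 20 at 30 and 15, the choice itself favours this order. For 60 to 15 minutes the immediate early median was 0.99, with 12 of 25 members at least 2-fold higher and 1 lower. NF-kB targets had a median of 1.84 over 4 members and p53 targets 0.94 over 3. The heat shock median was 0.23, that of G2/M -0.39 and that of S phase -0.24. Marker lists for 60 to 15 minutes stood at -0.64 for podocytes, -0.59 for mural cells, -0.51 for nephron progenitors and -0.49 for stroma. Endothelial, erythroid and nephron intermediate lists were at -0.42, -0.34 and -0.21. Intercalated, proximal tubule, loop of Henle, distal tubule and duct lists were above 0, at 0.52, 0.44, 0.33, 0.27 and 0.25. This comparison and 15 minutes to cold share the 15-minute library with opposite signs, which by itself favours opposite ratios.

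The comparisons with cold share that library, which makes their ratios correlate without any effect. Across 3364 genes, which are not independent replicates, Pearson's r between 15 and 60 minutes to cold was 0.803, beside 0.535 in simulations with shared cold counts and no effect, and the covariance was 0.156 beside 0.000753. Without the immediate early genes this r was 0.558. The simulations held counting noise only, so any trait particular to the 1 cold library could also raise the correlations and covariances. All 18 genes at least 2-fold higher at 15 minutes in this set were also among the 54 at 60 minutes, where independence would give 0.289; part of this excess may come from the shared cold library. The r was 0.896 for 30 with 60 minutes and 0.889 for 15 with 30 minutes, beside 0.552 and 0.586 in the simulations, and 0.797 and 0.619 without the immediate early genes. The covariances were 0.192 and 0.146, beside 0.000752 and 0.000756. Between 15 minutes to cold and 60 to 30 minutes, which share no library, r was 0.111, or 0.307 without the immediate early genes, and Spearman's rho 0.280, with a covariance of 0.00962.

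The shares of cells with a UMI give the same comparison per cell. After thinning to 800 UMIs per cell, with 637, 818, 754 and 299 shallower cells left out in the cold, 15-, 30- and 60-minute libraries, Fos was seen in 0.119% of cold cells (0.0596 to 0.213) and in 37.4%, 57.1% and 35.1% of cells at 15, 30 and 60 minutes. Without thinning these shares were 0.375%, 53.7%, 75.4% and 56.4%. Thinned shares for Egr1 were 1.81%, 40.8%, 51.5% and 23.6%, for Jun 5.62%, 32.5%, 47.6% and 40.3%, and for Atf3 0.325%, 1.56%, 10.97% and 20.6%. Unthinned, Egr1 was seen in 3.80%, 59.6%, 72.7% and 43.7% of cells, Jun in 14.2%, 51.8%, 68.5% and 63.5%, and Atf3 in 0.842%, 4.64%, 22.0% and 36.6%. Hspa1a was seen in 0.488%, 0.570%, 1.05% and 2.63% of thinned cells (unthinned 1.45%, 2.11%, 4.49% and 8.32%) and Hspa1b in 0.727%, 0.420%, 0.681% and 1.39% (unthinned 2.202%, 1.76%, 3.09% and 5.32%). Free RNA sets a background for such shares. In endothelial-like cells, which should lack them, the loop of Henle gene Umod was seen in 1.73%, 0.799%, 1.63% and 0.263% of thinned cells and the proximal tubule gene Kap in 3.46%, 1.70%, 4.88% and 3.55%. In their own classes these were seen in 39.9%, 34.1%, 37.4% and 36.3% (Umod) and 55.8%, 42.6%, 43.0% and 41.7% (Kap). Median depths were 1326, 1585, 1874 and 1602 UMIs in endothelial-like cells, 2092, 2132, 2034 and 3079 in loop-like, and 1727, 2133.5, 2111 and 2638 in proximal tubule-like cells. The Six2 share, a nephron progenitor gene, was 2.05%, 3.01%, 2.73% and 2.23% in nephron progenitor-like cells (median depths 1987.5, 1887, 2034.5 and 2259.5) and 0.133%, 0%, 0% and 0.263% in endothelial-like cells, where 0 of 1001 and 0 of 984 cells allow up to 0.2997% and 0.305% by a limit of 3 counts, or 0.368% and 0.374% by the exact interval. The shares for Hspa1a and Hspa1b lay within or below the range of this background in every library. So did those for Fos, Egr1 and Atf3 in cold and Atf3 at 15 minutes. Free RNA of a gene depends on that gene's own abundance, which was not matched here. The range therefore does not tell whether these UMIs came from free RNA.

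Cells fell into 31 clusters, from which 11 classes were rebuilt with fixed markers. Stroma-like cells, led by genes such as Col3a1 and Penk, made up 10.3% (9.71 to 10.9) of cold cells and 21.1%, 15.8% and 15.0% of cells at 15, 30 and 60 minutes. Mural-like cells (Rgs5, Acta2) made up 2.93%, 5.51%, 4.64% and 4.04%. Loop of Henle-like cells (Umod, Slc12a1) made up 11.8% (11.1 to 12.4) of cold cells and 5.24%, 7.80% and 6.27% later. Ureteric and collecting duct-like cells (Aqp2, Ret) made up 9.22%, 3.85%, 5.37% and 5.21%, and distal tubule-like cells (Slc12a3, Pvalb) 6.15%, 2.86%, 5.61% and 4.50%. Podocyte-like cells (Nphs1, Cdkn1c) made up 5.70%, 8.72%, 7.34% and 7.75%, nephron progenitor-like cells (Cited1, Crym) 14.6%, 18.8%, 17.8% and 19.5%, and nephron intermediate-like cells (Sfrp2, Fgf8) 11.98%, 9.72%, 10.9% and 9.45%. Proximal tubule-like cells (Kap, Lrp2) made up 7.17%, 5.28%, 6.39% and 7.78%, endothelial-like cells (Plvap, Kdr) 8.74%, 9.47%, 8.76% and 9.64%, and macrophage-like cells (C1qa, Lyz2) 0.812%, 1.21%, 0.856% and 0.976%. By a size of 1.5-fold to cold, mural-, podocyte- and stroma-like shares were higher and loop-, distal tubule- and duct-like shares lower at 15 minutes. At 30 minutes mural- and stroma-like shares were higher and loop- and duct-like shares lower, and at 60 minutes 0 of 11 were higher and the loop- and duct-like shares were lower. With genes scaled over all libraries together the stroma-like share was also higher at 60 minutes, which gives 1 class, and the proximal tubule-like share was lower at 15 minutes. The podocyte-like share at 15 minutes no longer reached this size at 0.5 and 2 times the resolution, where it was 7.32% and 7.24% in cold and 10.8% and 10.6% at 15 minutes. With all variable genes the macrophage-like share also passed at 15 minutes, and with at least 1000 genes per cell the distal tubule-like share was lower at 30 minutes and the macrophage-like share at 60.

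The shares themselves moved with the clustering. At 2 times the resolution nephron progenitor-like cells made up 7.60%, 8.24%, 8.58% and 9.33% in the order of cold, 15, 30 and 60 minutes, mural-like cells 1.25%, 2.71%, 2.25% and 1.82%, and nephron intermediate-like cells 7.42%, 7.21%, 7.13% and 7.53%, while unnamed clusters held 20.3%, 21.8%, 22.2% and 21.3%. Among cells with at least 1000 genes, nephron intermediate-like cells made up 23.9%, 20.1%, 19.7% and 20.1%, and podocyte-like cells 3.55%, 6.37%, 4.44% and 3.71%. In that set distal tubule-like cells made up 3.51% at 30 minutes and macrophage-like cells 0.515% at 60. With genes scaled over all libraries together the nephron intermediate-like share at 15 minutes was 14.7%, and with all variable genes unnamed clusters held 13.2% at 30 minutes.

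Unnamed clusters held 10.6%, 8.24%, 8.72% and 9.84% of cells. The largest, led by Osr2 and Hnf4a, held 5.26%, 3.95%, 3.84% and 3.92%, and 95.6% of its cold cells with a type from the authors were proximal tubule. Another, led by Pcp4 and Akap12, held 1.502%, 1.94%, 2.11% and 2.44%. A cluster led by Aqp2 and Aqp4 with intercalated markers held 2.53%, 1.07%, 1.35% and 1.52%, a cluster led by Cryab and Bst1 1.11%, 0.686%, 0.588% and 0.893%, and a cluster led by Calb1 and S100g, whose cells had 5.60 times the median UMIs of their library, 0.223%, 0.590%, 0.839% and 1.07%. The authors' lists of cold cells left 5003 of the 9856 without a type. Of their endothelial cells 98.0% fell in the endothelial-like class, of loop of Henle 94.4%, of cap mesenchyme 90.8% in nephron progenitor-like, of ureteric bud 83.3%, of stromal 74.3% with a further 22.5% in mural-like, of podocytes 67.9%, of distal tubule 66.4%, and of proximal tubule 49.8% with 39.1% in unnamed clusters. Of their nephron progenitors, 55.3% fell in nephron intermediate-like and 26.5% in nephron progenitor-like clusters.

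**Figure D2:**
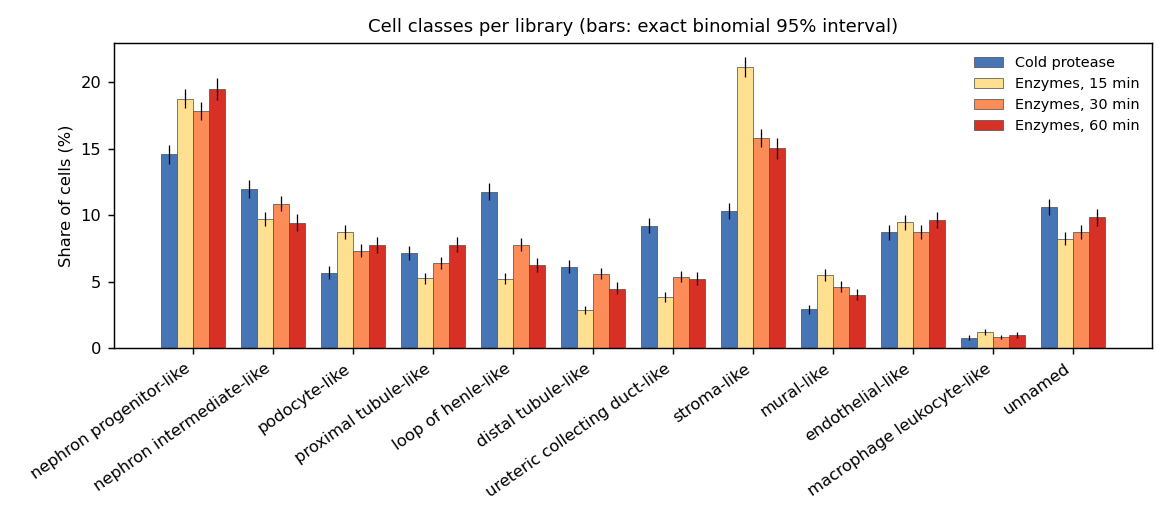
Share of cells (y axis, percent) in each rebuilt class (x axis) for the 4 libraries, with exact binomial 95% intervals as bars. Stroma-like cells made up 10.3% of the cold library and 21.1%, 15.8% and 15.0% of the 15-, 30- and 60-minute libraries, and loop of Henle-like cells 11.8% against 5.24%, 7.80% and 6.27%.

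The immediate early genes were higher than in cold within each of the 11 classes at all 3 times, and by more in tubule and duct classes than in endothelium. Over the members measured in each class, which differ between classes, the list's median at 60 minutes ran from 2.36 in endothelial-like to 5.39 in distal tubule-like cells, at 30 minutes from 2.56 in endothelial-like to 4.93 in duct-like cells, and at 15 minutes from 1.79 in endothelial-like to 4.25 in proximal tubule-like cells. With the same 13 genes in every class, the 60-minute medians were 5.39 in distal tubule-, 5.17 in duct-, 4.84 in loop-, 4.82 in proximal tubule-, 4.57 in podocyte-, 4.20 in nephron progenitor-, 4.04 in nephron intermediate-, 3.98 in mural-, 3.03 in stroma-, 2.89 in macrophage- and 2.196 in endothelial-like cells. With the same 13 genes at 30 minutes the medians ran from 2.82 in endothelial-like to 5.24 in proximal tubule-like cells. With the same 9 genes at 15 minutes they ran from 2.29 in mural-like to 5.40 in duct-like cells, with 3.23 in endothelial-like cells. The heat shock list at 60 minutes ran from -0.12 in macrophage-like to 0.40 in endothelial-like cells, with a median over 1 in 0 of 11 classes. The NF-kB list ran from 0.83 in nephron progenitor-like to 4.03 in proximal tubule-like cells. The p53 list ran from 0.23 in nephron progenitor-like to 2.05 in mural-like cells. For these lists too the members measured can differ between classes, and for NF-kB and p53 no same-gene values were made.

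Fos and Fosb were among the 3 highest genes at 60 minutes in most classes. A bound against 0 UMIs in cold does not rank a gene against the others. Such bounds take the 0 as 3 counts and are not the lower limits of the 95% intervals. For Fosb in nephron progenitor-like cells that limit was a log2 ratio of 8.69, beside 8.99 for the bound. In nephron progenitor-like cells Fos, with 2826 UMIs against 2, had a log2 ratio of 10.23 (8.38 to 13.28), Fosb had 0 UMIs in cold and was at least 509-fold higher, and Nr4a1 stood at 7.60. Atf3 joined them in nephron intermediate-like cells at 7.74, where Fos was at 8.71 and Fosb at least 287-fold higher. In podocyte-like cells Fos, with 1665 UMIs against 0, was at least 548-fold higher, while Nr4a1, with 974 against 1, stood at 9.91 (7.43 to 15.22) and Atf3, with 632 against 1, at 9.29 (6.80 to 14.59). Proximal tubule-like cells had Atf3 at 9.12 (7.26 to 12.17), Fos at 9.04 (6.55 to 14.34) and Fosb at least 94.99-fold higher. Loop-like cells had Fos at 10.10, Fosb at least 601-fold higher and Atf3 at 8.62. Distal tubule-like cells had Fos at 8.82, Fosb at least 255-fold higher and Socs3 at 7.99. Duct-like cells had Fosb at 10.08, Fos at 9.68 and Atf3 at 8.42. Stroma-like cells had Fosb at 9.16, Fos at 8.21 and Hc, the gene of complement component C5, at 7.25 (4.76 to 12.56). Mural-like cells had Socs3 at 8.67 (6.19 to 13.98), Fos at 7.44 (6.08 to 9.32) and Tnfsf9, a costimulatory ligand gene, at 6.65 (4.15 to 11.96). Endothelial-like cells had Fosb at least 235-fold higher, Fos at 7.69 and Nr4a2 at 4.86. In macrophage-like cells the highest were the chemokine genes Cxcl2 at 7.60 (5.10 to 12.91) and Ccl4 at 6.60 (4.73 to 9.66), and the neutrophil granule gene Ngp at 6.49 (3.97 to 11.81).

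**Figure D3:**
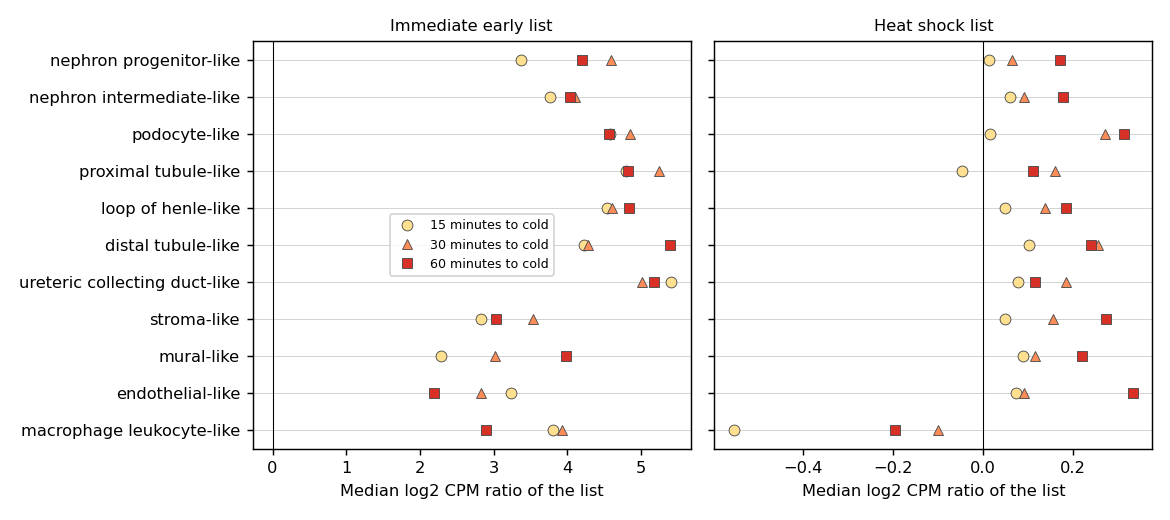
Median log2 CPM ratio to cold (x axis) of the immediate early and heat shock lists in each rebuilt class (y axis) at 15, 30 and 60 minutes, over the members measured in all 11 classes. At 60 minutes the immediate early medians ran from 2.196 in endothelial-like to 5.39 in distal tubule-like cells and the heat shock medians from -0.20 in macrophage-like to 0.33 in endothelial-like cells.

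The genes highest for 60 to 15 minutes differed in level between classes. Cldn4 at 60 minutes was at 2641 CPM in duct-like cells, a log2 ratio of 4.67 (4.52 to 4.83) to cold, and at 750 CPM in distal tubule-like cells, a ratio of 3.59. F3 was at 530 CPM in duct-like cells, a ratio of 4.16, and at 370 CPM in proximal tubule-like cells, a ratio of 5.44. Sprr1a was at 452 CPM in duct-like cells, a ratio of 4.09 (3.78 to 4.42), while in nephron intermediate-like cells it stood at -1.26 and in stroma-like cells at -2.90. Over the whole cold library Sprr1a was at only 7.92 CPM. The negative ratios may thus rest on few UMIs, and no opposite direction between classes is read from them. Krt18 was at 3343 CPM in duct-like cells, a ratio of 2.19. Most UMIs of Ren1 were in mural-like cells, with 3476 of 3612 UMIs at 60 minutes. Within this class Ren1 was higher than in cold by 1.47, 0.72 and 1.06 at 15, 30 and 60 minutes. Over cells of all classes with at least 1000 genes it stood at -0.76 at 60 minutes.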

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

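The tests of scaling, of the share of genes with an AU-rich motif, of the Fos to Atf3 ratio between classes, and of enzymes and temperature apart from time were chosen after the results were seen. Mt2, a metallothionein gene, drew attention because it differed in opposite directions between classes at 60 minutes to cold: its log2 ratio was 1.34 (1.25 to 1.42) in distal tubule-like cells and -1.75 (-2.41 to -1.13) in macrophage-like cells, and the difference was not tested. S100a8, a neutrophil gene, did so too, at 4.98 (3.41 to 7.28) in stroma-like cells and -4.34 (-6.66 to -2.72) in podocyte-like cells, with 2 classes at least 2-fold higher and 1 lower, and the difference was not tested. A signal also appeared in the 3477 barcodes of the 15-minute library with under 500 genes, which no main comparison used. They held Fos at 549 CPM (521 to 579), beside 879 CPM in the kept cells of that library and 1.68 CPM in the cold library. Those barcodes had a mitochondrial share of 19.7%.

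The 12 genes named as lowest at 60 minutes had a median log2 ratio to cold of -1.15. A different mix of cell classes is argued against, since with classes weighted alike the median was -1.21, and of 77 pairs of gene and class 76 were below 0 and 70 had an interval below 0. Scaling to totals that hold the response genes is argued against as the whole cause. Median-of-ratios size factors raise every ratio alike by 0.13, which left the median at -1.01. With them 6 genes were at least 2-fold lower instead of 11, so scaling bears on the count. Loss of short-lived transcripts during digestion could account for the pattern and stays open: an AU-rich motif stood in the 3′ UTR of 45.5% of the 11 genes with an annotated one, beside a median of 27.3% in random lists (percentile 86.5), but also in 38 of the 88 genes at least 2-fold higher at 60 minutes with an annotated one, and the planned measure, motif density, had a median of 0 in both and so decides nothing. The biological explanation that the design names, a response to the enzyme digestion, stays open and untested.

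Stroma markers were higher at 15 minutes than in cold, with a list median of 0.71. A different mix of cell classes is a candidate explanation, since the median was 0.037 with classes weighted alike and -0.01 within stroma-like cells. Free RNA from lysed stromal cells cannot be told apart from it in part: the median over the 9 classes other than stroma and mural was 0.36, between the bounds set for either outcome. Whether the enzyme cocktail releases more stromal cells or the cold protease more tubule cells was not tested, and neither was a biological difference between the mice.

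Immediate early genes were higher than in cold in all 11 classes at all 3 times. Free RNA from a few responding cells is argued against as the whole cause, since such RNA would keep Fos and Atf3 in 1 ratio, whereas at 60 minutes the ratio of their UMIs differed 18.3-fold between classes, from 0.448 in duct-like to 8.22 in nephron progenitor-like cells. Cells over 25% mitochondrial, 4.21% of the cells at 60 minutes, are argued against as the whole cause too. Without such cells the median at 60 minutes was lower by only 0.049 (3.74). Cells with a lesser mitochondrial share were not tested. Enzymes and temperature apart from time cannot be told apart, because no library separates enzyme from temperature and the labels give no temperatures. The list was already at 3.17 at 15 minutes, the shortest digestion. A response of the cells to digestion could give the pattern and stays a hypothesis, with 1 library per condition.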

How the results depend on the processing

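Leaving out the cells with the highest Scrublet scores was chosen after seeing the data. The 6 counts of genes at least 2-fold different stayed within 1.5 times in 66 of 84 values and moved in 18. Some of the values that stayed, here and for lists and named genes, could not move. At 30 and 60 minutes the settings of at least 300 genes and of every barcode left the same cells. Scrublet's own calls removed at most 1 cell of a library. Of 1080 list medians, 663 stayed within their counting interval, 401 moved and 16 changed sign. For named genes, 1321 of 1800 values stayed, 478 moved and 1 changed sign. Class shares stayed in 103 of 220 values and moved in 117, counts of classes, though not always which classes, stayed in 29 of 30, and shares with a UMI, which no thinning raises by construction, moved in 49 of 56. The immediate early median stayed above 0 in every alternative, from 1.65 to 3.20 at 15 minutes, 3.10 to 4.17 at 30 and 3.06 to 3.92 at 60. Shallow classes and genes near 50 CPM set the limits of depth, and no value here covers variation between mice. No paired analysis was possible because each group holds 1 library. No erythroid-like class was found, so only the macrophage-like class was left out. Where no cause is named below, the cause was not tested.

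Among cells with at least 1000 genes, the immediate early median was 3.84 at 30 minutes (main 4.11) and 3.86 at 60 (3.79), the proximal tubule median at 15 minutes 0.063 (-0.31), the mural median -0.21 at 30 minutes (0.39) and -0.76 at 60 (0.29), and Ren1 at 60 minutes -0.76 (1.34). With every deposited barcode the heat shock median at 15 minutes was -0.0072 (0.030).

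By construction, other scalings shift every gene alike. Median-of-ratios size factors gave 6 lower genes at 60 minutes (11), an immediate early median of 3.92 and a heat shock median of 0.57 (0.44). TMM gave 2 lower genes at 30 minutes (4) and 7 at 60, immediate early medians of 4.17 and 3.90, and heat shock medians of 0.15 (0.10) and 0.55. Without mitochondrial, ribosomal protein and haemoglobin genes in the totals the heat shock median at 30 minutes was 0.061.

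The mean over cells of per-cell fractions, in which shallow cells weigh as much as deep ones, gave 39, 1 and 21 lower genes at 15, 30 and 60 minutes (0, 4 and 11), of which 0, 0 and 6 were shared. Its immediate early medians were 2.89, 3.74 and 3.40, its heat shock medians -0.010 at 15 and 0.27 at 60 minutes, its podocyte medians 0.088 at 30 and 0.088 at 60 minutes (-0.33 and -0.31), and its proximal tubule median at 60 minutes -0.13 (0.19). The deposited normalized signal is the same quantity, and its means gave the same 2.89, 3.74, 3.40, -0.010, 0.27, 0.088, 0.088 and -0.13.

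With classes weighted alike, the immediate early medians were 2.98, 3.86 and 3.38, the heat shock median at 60 minutes 0.29, and 0 genes were lower at 30 minutes. The podocyte median was -0.077 (0.29) and the distal tubule median 0.023 (-0.39) at 15 minutes, the mural median -0.049 at 30 and -0.15 at 60 minutes, and the proximal tubule median at 60 minutes -0.14. Without cells over 25% mitochondrial the loop of Henle median at 30 minutes was 0.013 (-0.12).

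A lower expression minimum tests more genes, at more counting error. At 10 CPM 49, 88 and 197 genes were higher (20, 42 and 98), and 7 and 110 lower at 30 and 60 minutes; 64.2% of those at 60 minutes were higher, beside 89.9%. The immediate early medians were 2.27, 3.10 and 3.06, the heat shock median at 15 minutes 0.12, and the nuclear-retained median at 60 minutes 0.10 (-0.30). With no minimum beyond 1 UMI in both libraries, 1136, 834 and 1696 genes were higher and 1051, 1447 and 1603 lower, with immediate early medians of 1.65 at 15 and 3.22 at 30 minutes and a heat shock median at 15 minutes of 0.092. With genes scaled over all libraries in the clustering, 1 class was at least 1.5-fold higher at 60 minutes (0).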

Other observations

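Named genes outside the AP-1 family differed in level between classes at 60 minutes. Gdf15 was at 450 CPM in duct-like cells, a log2 ratio to cold of 5.75 (5.22 to 6.35), and at 49.0 CPM in distal tubule-like cells, a ratio of 4.41. Hspa1a was at 154 CPM in loop of Henle-like cells, with 699 UMIs against 31 and a ratio of 4.73 (4.21 to 5.29), while in proximal tubule-like cells it was at 15.2 CPM, a ratio of 2.06. Socs3 stood at 8.67 in mural-like, 8.02 in loop-like and 6.24 in podocyte-like cells, and at 2.13 (1.67 to 2.62) in nephron progenitor-like cells.

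Of the genes named as lower at 60 minutes, Rprm was at 211 CPM at 60 minutes and 730 CPM in cold within duct-like cells, a log2 ratio of -1.79 (-1.93 to -1.66). Emx2 was at 61.3 and 394 CPM in duct-like cells, a ratio of -2.68 (-2.93 to -2.45), and at -1.20 in nephron intermediate-like cells. Gata3 had 239 UMIs at 60 minutes and 265 in cold in distal tubule-like cells, a ratio of 0.063 (-0.20 to 0.32), so no difference was detectable there. These ratios were chosen for mention after their values were seen.

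Within classes at 60 minutes to cold, genes at least 2-fold higher and lower numbered 245 and 103 of 3657 in duct-like cells, 84 and 5 of 3502 in loop-like cells, 115 and 12 of 3236 in distal tubule-like cells, 104 and 27 of 3417 in proximal tubule-like cells, 63 and 38 of 3514 in nephron intermediate-like cells, 143 and 112 of 3797 in podocyte-like cells, 112 and 90 of 3742 in endothelial-like cells and 35 and 35 of 3330 in nephron progenitor-like cells. More genes were lower than higher in stroma-like cells, with 46 and 62 of 3480, and in mural-like cells, with 116 and 165 of 3677. The median log2 ratio over all these genes was -0.138 in stroma-like and -0.142 in mural-like cells. Such a shift by itself favours lower genes in the count, and no other scaling was tried within classes. The classes differ in depth, and in the macrophage-like class, with 82 and 80 cells, the counts were 408 and 843 of 3927.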
